A study of Mus musculus with 4 samples.

How the data were processed

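Single-cell RNA sequencing was done on dissociated intestinal epithelium of Crl:CD1(ICR) mice, an outbred stock. The 4 libraries cross tissue fraction (whole epithelium or isolated crypts) with treatment (none, or 12 Gy of whole-body irradiation), with 1 library per group. Per the labels' protocols, tissue was dissociated with trypsin, a hand-counted 4500 cells per sample were loaded for 10x Genomics droplet capture, and libraries were read on an Illumina HiSeq instrument. The time between irradiation and sampling and the number of animals behind a library are not given in the sources used here. In this protocol, each captured transcript carries a unique molecular identifier (UMI), so a count is a number of distinct tagged molecules.

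Raw UMI counts per gene and barcode were deposited by the authors as 1 sparse matrix per library, each with 27998 genes and 4500 barcodes. Cell Ranger 2.0, Seurat (with no version) and the mm10 genome build are named per the submitters' processing notes; the annotation release is not given in the sources used here. Natural log values were also deposited by the authors, in 1 table for the crypts and 1 for whole epithelium. These were checked against the counts. In the whole-epithelium table, 100% of the values above 0 equalled the natural log of 1 plus the count scaled to 10000 UMIs per cell, within a tolerance of 0.001. In the crypt table this held for 99.0% of values when UMIs of mitochondrial genes were left out of the total, and for 0.147% when they were left in. The deposited tables held 4485 and 4225 cells of normal and irradiated whole epithelium and 2882 and 3762 of normal and irradiated crypts, and every one of these barcodes was found in the raw matrices. The highest mitochondrial share of a cell in them was 88.2% and 92.5% in whole epithelium and 38.5% and 61.0% in crypts. All results below come from the raw counts, because they are not log-transformed and cover the same barcodes in each library. The log tables were used only for this check and for 1 alternative barcode set.

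Barcodes were kept as cells when they had at least 500 detected genes and at most 20% of UMIs from mitochondrial genes, which passed 2003 barcodes of normal whole epithelium, 1087 of irradiated whole epithelium, 2403 of normal crypts and 2196 of irradiated crypts. Doublets were called per library with Scrublet. It called 13, 12 and 19 cells in normal and irradiated whole epithelium and irradiated crypts, which were removed. In normal crypts it called 0.499% of cells, under the fixed limit of 0.5%, so the 4% of cells with the highest scores were removed instead (96 cells). Doublet removal therefore differed between normal crypts and the other 3 libraries. The 4 libraries kept 1990, 1075, 2307 and 2177 cells in the same order. Kept cells were 44.2%, 23.9%, 51.3% and 48.4% of the deposited barcodes, so the mitochondrial filter bears on every share of cells given below.

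Kept cells of all libraries were scaled to 10000 UMIs, log-transformed and clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm at resolution 1, without batch integration. A cluster was called X-like from 14 marker sets fixed before the data were examined. The rule for applying the markers was set after the clusters were seen: at least 3 markers of the class 2-fold above the other cells and detected in at least 20% of the cluster's cells, and no more markers of another class than of its own among the 10 leading genes by fold with at least 50 CPM (the count as a share of the total, scaled to 1000000). Clusters that did not meet it stayed unnamed. Because clusters can follow the genes that differ between libraries, shares of classes are given from a second clustering that left out the 2020 genes meeting the size rule between irradiated and normal in either fraction, with the first clustering beside it. No stromal, erythroid or pancreatic acinar cluster was named.

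For comparisons of expression, counts of all kept cells were summed per library and scaled to CPM by the library's total. With 1 library per group no test between conditions was made, there is no replicate check, and no p-value is given. A model of treatment plus fraction would leave 1 residual degree of freedom and take every difference between the fractions as error, and it was not fitted. Each ratio of CPM values carries an exact 95% conditional binomial interval (Clopper-Pearson), each CPM value an exact Poisson interval and each share of cells an exact binomial interval. All intervals cover counting error only and compare these libraries, not the conditions. A gene met the size rule when its higher CPM was at least 20, its absolute log2 ratio at least 1 and the nearer bound of its interval beyond 1.5-fold. Where 1 library had a count of 0, the ratio was taken against a floor of 3 counts per library and is given as "at least"; a share of 0 is given with the upper limit that 3 counts allow. The rule was tested on simulated data with known answers, with 27998 genes for each of the 4 comparisons and 200 genes of at least 20 CPM changed. All genes set to 3-fold or 6-fold met it in the right direction, none set to 1.5-fold did, and 0 unchanged genes did. The intervals covered the true ratio in 95.1% of genes for irradiated against normal crypts, 95.4% for whole epithelium, 95.4% for normal crypts against whole epithelium and 95.6% for the irradiated pair.

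Before the data were examined, 26 gene lists were fixed. For each list, the median log2 ratio of its members with a mean CPM of at least 5 was placed among 10000 random lists of the same size matched on mean expression over 20 bins. Its percentile describes these libraries and is not a test. The interval given with a median is an order-statistic interval over the list's members, and members at 0 in 1 library entered at their floor. In simulated data with 2000 random lists, none of the 26 unchanged lists fell outside the central 95% in either fraction, and a p53 list shifted by 0.5 (log2) reached percentile 100. Apart from the changed genes, these simulated counts varied by counting error alone, independently for each gene. The simulation therefore checks the calculation and does not show how lists of genes that vary together behave in the real libraries. One list was taken from what is known of the study itself and is named "from the study". Some lists share genes. The stem cell and Wnt lists share 6, and the revival stem cell list shares 2 each with the YAP, fetal and matrix lists and 1 each with the p53 and Wnt lists. The p53 list also shares 1 with the immediate early list, the villus tip list 1 each with the YAP, fetal and goblet lists, and the matrix list 1 each with the fetal and Wnt lists. Of the genes that also named clusters, 16 are in the Paneth list, 12 in the stem cell list, 10 in the G2 and M list, 9 in the goblet list and 8 in the fetal list.

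The share of cells with a Clu UMI was taken after thinning each cell to 2000 UMIs and leaving out shallower cells, with T or NK-like cells treated alike as the background from free RNA. Genes named in the text were chosen by a rule fixed before the data were examined. The rule took the first 12 in each direction among genes meeting the size rule in the same direction in both fractions, ranked by the smaller absolute log2 ratio. It took the first 5 in each direction in each fraction with an absolute log2 ratio under 0.5 in the other, and the first 8 in each direction for crypts against whole epithelium in both treatments. It added up to 4 members per list with the largest absolute log2 ratio in crypts and a CPM of at least 20, and 9 genes named in advance. Immunoglobulin and T-cell receptor segments were skipped. This gave 150 genes; others are named as chosen after their values were seen. Coordinates and strand were matched by gene identifier to GENCODE vM21 (GRCm38), which held 27645 of the 27998 genes.

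Alternatives fixed before the data were examined were all barcodes, a stricter filter (1000 genes, 10% mitochondrial UMIs), the barcodes of the authors' tables, called doublets kept, TMM scaling, no minimum CPM, Leiden resolutions 0.5 and 2, clustering without the genes that differed between irradiated and normal libraries, other thinning depths, at least 2 Clu UMIs, Clu shares over all kept cells, other minimum list expression, and ratios standardised to equal cell makeup over classes with at least 50 cells in both libraries. Added after the data were seen were sums within enterocyte-like, goblet-like, enteroendocrine-like or T or NK-like cells alone, sums over epithelial clusters alone, and list medians in enterocyte-like cells alone. A comparison within stem-like and transit-amplifying-like crypt cells had been fixed too but could not be made, since irradiated crypts held 1 such cell in the first clustering. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors only. Whether counting used strand is not given in the sources used here, so genes overlapping on opposite strands cannot be told apart.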

Results

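The series asks how the intestinal epithelium differs, cell by cell, between unirradiated mice and mice given 12 Gy of whole-body radiation, and its title names a revival stem cell, a damage-induced crypt cell that the study is known to mark by Clu. Single-cell RNA profiles were measured in 4 libraries of Crl:CD1(ICR) mice, which are outbred. The libraries were whole epithelium and isolated crypts of unirradiated ("normal") and irradiated mice, 1 library each. Each held 4500 barcodes, with a median of 6301 UMIs per barcode in normal whole epithelium, 4329 in irradiated whole epithelium, 6986.5 in normal crypts and 5111 in irradiated crypts. Total UMIs were 54292816, 35335425, 76291710 and 53704744 in that order.

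The median share of mitochondrial UMIs per barcode was 27.1% in normal and 42.8% in irradiated whole epithelium, and 14.5% in normal and 21.7% in irradiated crypts. After filtering, 1990, 1075, 2307 and 2177 cells remained, with 40699545, 18966514, 64115843 and 41528110 UMIs. Their median depths were 18270 UMIs and 3682.5 genes in normal whole epithelium, 11014 UMIs and 2685 genes in irradiated whole epithelium, 23170 UMIs and 4102 genes in normal crypts, and 9948 UMIs and 2480 genes in irradiated crypts. Every value below comes from 1 library per group and has no replicate check. Bracketed ranges are 95% intervals that cover counting error only, and "higher" and "lower" compare these libraries. For summed counts they leave out the sampling of cells, so a gene made by few cells is less certain than its range.

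Transit-amplifying-like cells, the dividing progenitors of the crypt, made up 16.2% (14.6 to 17.9) of kept cells in normal and 0.279% (0.0576 to 0.813) in irradiated whole epithelium. In crypts they were 24.5% (22.8 to 26.3) and 0.459% (0.22 to 0.843). Revival stem-like cells were 0 of 1990 and 0 of 2307 cells in the normal libraries, which allows shares of up to 0.151% and 0.130%. They were 2.51% (1.66 to 3.63) of irradiated whole epithelium and 11% (9.74 to 12.4) of irradiated crypts. Such limits for a class at 0 cover counting only, since names go to clusters and a few such cells could sit in other clusters. Markers of the revival stem-like class, among them Clu, Anxa1 and Ly6a, themselves differed between irradiated and normal libraries. T or NK-like cells were 8.09% (6.93 to 9.38) of normal and 15% (12.9 to 17.3) of irradiated whole epithelium, and 5.29% (4.41 to 6.28) of normal and 30.4% (28.5 to 32.4) of irradiated crypts. Myeloid-like cells were 0.217% (0.0704 to 0.505) of normal and 1.47% (1.01 to 2.07) of irradiated crypts. These shares come from the clustering without the genes that differed between irradiated and normal libraries, and the mitochondrial filter, which kept 23.9% to 51.3% of barcodes, can set them. The revival stem-like cells came only from the irradiated libraries in both clusterings, and 1 library per group does not separate the treatment from other differences between those libraries and the normal ones.

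Enterocyte-like cells were 49.2% (47.0 to 51.5) and 60.7% (57.7 to 63.6) of normal and irradiated whole epithelium, and 31.7% (29.8 to 33.7) and 39.8% (37.8 to 41.9) of crypts. Paneth-like cells were 4.37% (3.52 to 5.36) and 2.23% (1.44 to 3.30) of whole epithelium and 10.7% (9.47 to 12.0) and 4.64% (3.79 to 5.61) of crypts. Of these, 41 of 87 and 14 of 24 whole-epithelium and 89 of 247 and 51 of 101 crypt cells had over 5% of UMIs from Defa24 and Defa20 under 5% of Defa24. Of all such cells, 11.8% and 94.7% in whole epithelium and 13.3% and 79.0% in crypts had goblet genes over 3 times the free-RNA level. Irradiated and normal Paneth-like cells may thus differ in kind. Goblet-like cells were 11.6% (10.2 to 13) and 14.6% (12.5 to 16.9) of whole epithelium, and 10.7% (9.51 to 12.1) and 6.71% (5.69 to 7.84) of crypts. With all variable genes the crypt direction depended on the resolution and on which clusters were named. Enteroendocrine-like cells stood at 2.61%, 3.35%, 3.16% and 4.36% and tuft-like cells at 1.01%, 0.837%, 0.737% and 1.06% in normal and irradiated whole epithelium and normal and irradiated crypts. B or plasma-like cells were 0.553% of normal whole epithelium and 0.607% of normal crypts, and 0 in the irradiated libraries, which allows up to 0.279% and 0.138%. Unnamed clusters held 6.33%, 0.093%, 12.3% and 0.0459%.

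**Figure D1:**
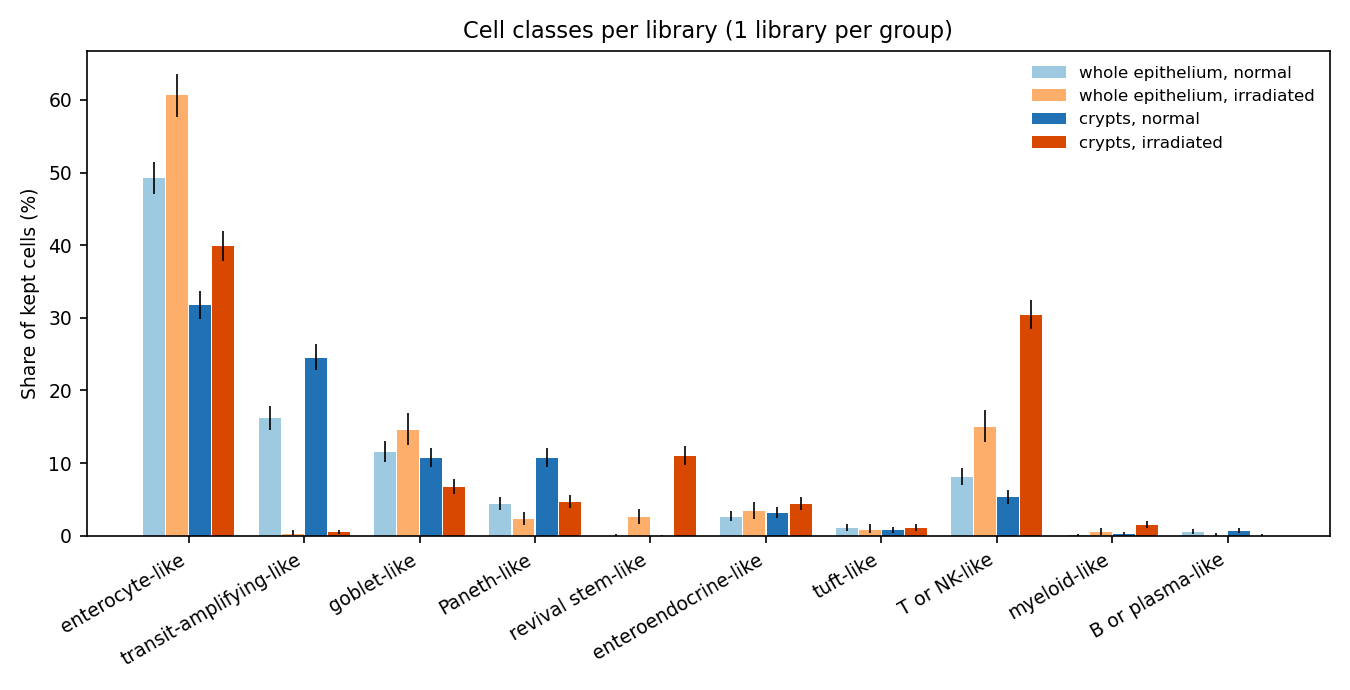
Share of kept cells (%) in each class, for normal and irradiated whole epithelium and crypts, from the clustering that left out the genes differing between irradiated and normal libraries. Bars are shares and error bars exact 95% binomial intervals (counting error only); transit-amplifying-like bars stand at 24.5% in normal and 0.459% in irradiated crypts, revival stem-like bars at 0% and 11%.

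With all variable genes, transit-amplifying-like cells were 14.3% and 0% of normal and irradiated whole epithelium and 22.3% and 0.0459% (1 cell) of crypts, and revival stem-like cells 2.98% and 12.0% of the irradiated libraries. A stem-like cluster, led by Lgr5, Gkn3, Ascl2 and Slc12a2, then held 12 normal whole-epithelium and 33 normal crypt cells and 0 irradiated cells. Unnamed clusters were 20.5% and 23.1% of the normal libraries and 0% and 0.0919% of the irradiated ones. They were led by Hbb-bs, Rbp7 and Gsdmc4, by Fabp6, or by Ccl9. The cluster led by Ccl9 had the goblet markers Ccl9, Agr2 and Tpsg1 among its leading genes, and cycling markers enriched but not leading. It held 77 normal whole-epithelium and 95 normal crypt cells, which count neither as goblet-like nor as transit-amplifying-like. In that clustering different clusters held the enterocyte-like, goblet-like and Paneth-like cells of the normal and irradiated libraries. Goblet-like and Paneth-like shares depended on the clustering. With all variable genes at resolution 1, goblet-like cells were 6.76% (5.77 to 7.86) of normal and 9.60% (8.39 to 10.9) of irradiated crypts, the opposite direction to that without the genes that differed, and 7.94% and 16.7% of normal and irradiated whole epithelium. At resolution 2 they were 6.81% (5.81 to 7.91) and 6.29% (5.31 to 7.40) of crypts, intervals that overlap, and 7.89% and 15.2% of whole epithelium. At resolution 0.5 they were 10.9% and 0.0459% of crypts and 11.8% and 0% of whole epithelium. An unnamed cluster there held 240 irradiated crypt and 181 irradiated whole-epithelium cells. The irradiated goblet-like and Paneth-like clusters of resolution 1 held similar numbers (209 and 31 crypt, 180 and 1 whole-epithelium cells). The low shares at resolution 0.5 may thus reflect naming and give no direction. Paneth-like cells were 10.4% and 1.61% of normal and irradiated crypts and 4.07% and 0.093% of whole epithelium with all variable genes at resolution 1. At resolution 2 they were 242 normal and 105 irradiated crypt cells and 81 and 17 whole-epithelium cells. At resolution 0.5 they were 240 and 4 crypt cells and 81 and 0 whole-epithelium cells. Of the myeloid-like cells, 1 cluster was then led by genes that include the MHC class II genes H2-Aa and H2-Eb1 and another by S100a8, Cxcl2 and S100a9. Without the cell filter, T or NK-like cells were 15.4% and revival stem-like cells 6.58% of irradiated crypt barcodes.

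Clu was among the genes furthest above normal in irradiated crypts. This gene (ENSMUSG00000022037, clusterin, a secreted chaperone; GRCm38 chromosome 14, 65968483 to 65981547) was at 253 CPM against 0.187, 1350.2-fold higher (773 to 2614). Ly6a, which encodes the surface antigen Sca-1, was 197-fold higher (167 to 234), and the annexin gene Anxa1 652-fold (299 to 1778). Sprr1a, a cornified-envelope precursor gene, was at 70.5 CPM against 0 counts, at least 1507-fold higher. Mki67, a marker of dividing cells, was at 15 against 78.9 CPM, 5.26-fold lower (4.84 to 5.73).

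Of 5538 genes with at least 20 CPM in either crypt library, 706 met the size rule higher and 664 lower in irradiated crypts, and without the minimum 2906 and 1753 did. Other high genes were Anxa10 at 57.4 against 0.0156 CPM and the adjacent Ly6-family genes Gml2, 1517-fold (518 to 7359), and Gml, 1148-fold (492 to 3539). Saa1, an acute-phase gene with near-identical copies, was 182-fold higher (128 to 271), and Mbl2, which encodes the complement-activating mannose-binding lectin, 146-fold (86.7 to 268). Among the genes furthest below normal were the cytochrome P450 gene Cyp2c66 at 0.241 against 26.4 CPM, 109.7-fold lower (59.5 to 229), the retinol dehydrogenase gene Rdh7, 83.9-fold (63.4 to 114), and the glucuronosyltransferase gene Ugt2b5, 74.2-fold (44.9 to 133). Some genes met the rule in crypts with a log2 ratio of under 0.5 in whole epithelium. Higher were the leukocyte genes Lcp1, 5.25-fold (4.72 to 5.84), Ccl5, 5.07-fold (4.99 to 5.15), and Hcst, 4.23-fold (3.77 to 4.77), beside a T or NK-like share of 30.4% against 5.29%. The hormone gene Sct (secretin) was 4.69-fold higher (4.57 to 4.81) and Bok, of the Bcl-2 family, 3.02-fold (2.8 to 3.27). Lower were the lipase gene Pnliprp2, 2.46-fold (2.34 to 2.59), the kallikrein gene Klk1, 2.33-fold (2.21 to 2.47), the immediate early gene Egr1, 2.21-fold (2.11 to 2.31), and Gas6, 2.15-fold (1.96 to 2.35). The globin gene Hba-a1 was 44.5-fold lower (37 to 54.1), and in normal crypts it stood at 8498 CPM in the 33 stem-like cells, 198 in unnamed clusters and 15.5 in T or NK-like cells.

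Gml2, Gml and Saa1 were among the genes furthest above normal in irradiated whole epithelium. Gml2 was at 111 against 0.0246 CPM (1 count), 4523-fold higher (811 to 178752), Gml at 162 CPM against 0 counts, at least 2202-fold, and Saa1 185-fold higher (126 to 284). Fut2, which adds fucose to mucosal glycans, was 107-fold higher (74.6 to 159), Ly6a 73.4-fold (59.8 to 91.3) and Clu, at 21.9 against 0.172 CPM, 127-fold (61.2 to 318). Rdh7 was 76.1-fold lower (55.6 to 107), Cyp2c66 89.9-fold (48.8 to 188) and Reg1, which encodes a secreted lectin, 40.1-fold (37.9 to 42.5). Smoc2, a stem cell gene, was 57.7-fold lower (30.3 to 127) and Mki67 16-fold (12.5 to 20.7).

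Of 5672 genes with at least 20 CPM, 746 met the size rule higher and 1017 lower in irradiated whole epithelium, and without the minimum 1852 and 2455 did. With a log2 ratio of under 0.5 in crypts, Afp (alpha-fetoprotein) was 7.79-fold higher (7.06 to 8.61), Atoh1, the transcription factor of the secretory lineage, 2.84-fold (2.56 to 3.15), and the kinase gene Plk3 2.7-fold (2.45 to 2.97). The chemokine gene Ccl6 was 2.64-fold higher (2.57 to 2.7) and Kdelr3, an endoplasmic reticulum retention receptor gene, 2.62-fold (2.28 to 3). The 5 furthest lower were alpha-defensin genes, which encode the antimicrobial peptides of Paneth cells: Gm21002, 67.1-fold (60.7 to 74.3), Defa22, 60.1-fold (55.7 to 65), Gm15308, 59.5-fold (54.1 to 65.7), Defa20, 55.9-fold (52.5 to 59.6), and Defa23, 50.8-fold (42.4 to 61.3). These genes lie in a cluster of near-identical copies, so reads shared between copies leave single members uncertain.

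Between the 2 fractions, 561 genes met the size rule higher and 550 lower in both, and 2 alpha-defensin genes, Gm10104 and Gm15293, met it in opposite directions. Ranked by the smaller of their 2 ratios, the first 12 higher genes were Gml2, Gml, Anxa10, Saa1, Mbl2, Clu, Fut2, 2010109I03Rik, Ly6a, Ly6d, Il18bp and Gm14085. Of these, Ly6d, Gml, Gml2, 2010109I03Rik and Ly6a lie within chromosome 15, 74762056 to 74998031, among Ly6-family genes of similar sequence. 2010109I03Rik was 463-fold higher in crypts (350.3 to 627) and 80.5-fold in whole epithelium (70.8 to 91.9), and Ly6d 124-fold (106 to 147) and 71.3-fold (57.6 to 89.5). Il18bp, which encodes the soluble inhibitor of interleukin 18, was 40.1-fold (32.8 to 49.5) and 42.2-fold (34.3 to 52.4) higher. The first 12 lower genes were Cyp2c66, Rdh7, Ugt2b5, Adh4, Slco2b1, Adck3, Gsdmc4, Rbp7, Gstm3, Ces1f, Cyp2b10 and Reg1. Adh4, an alcohol dehydrogenase gene, was 65.3-fold lower in crypts (40.1 to 114) and 63.6-fold in whole epithelium (33.4 to 139), and the anion transporter gene Slco2b1 85.7-fold (51.8 to 153) and 59.8-fold (32.4 to 125). The glutathione transferase gene Gstm3 was 43.4-fold (36.7 to 51.5) and 29.3-fold (24.9 to 34.8) lower and the carboxylesterase gene Ces1f 46.5-fold (38.3 to 57.1) and 29.0-fold (23.9 to 35.5).

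**Figure D2:**
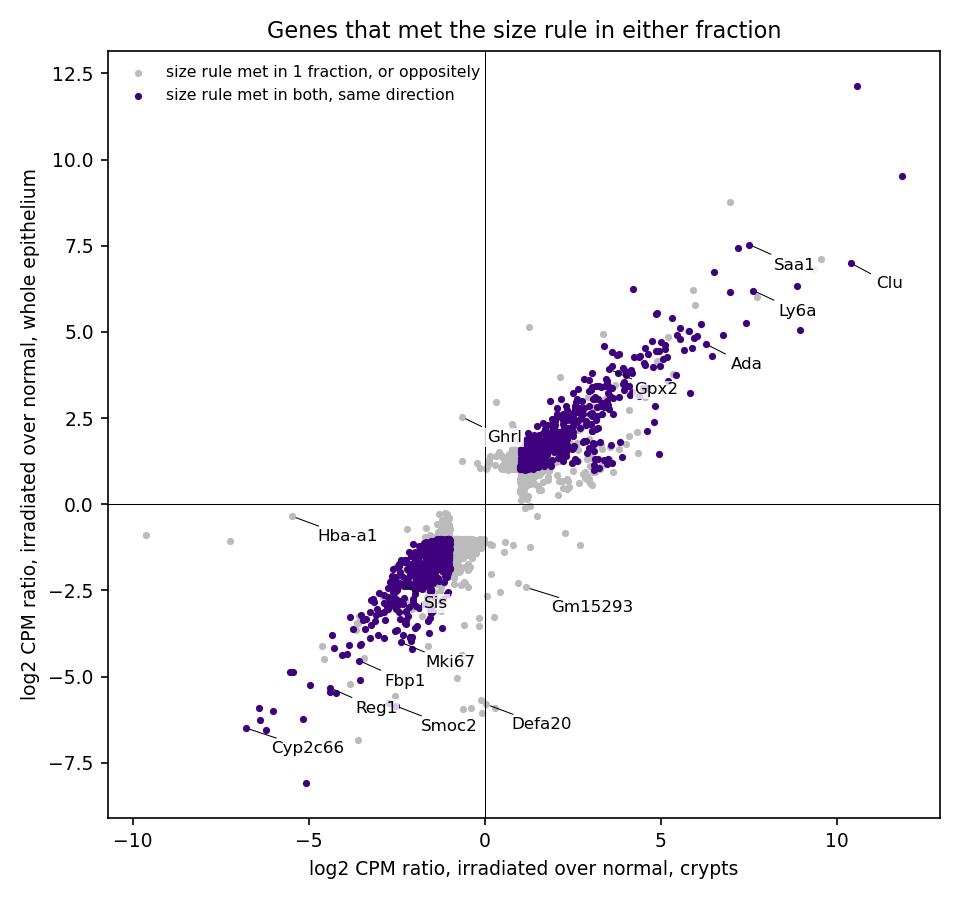
Log2 ratio of CPM, irradiated over normal, in crypts (x axis) and whole epithelium (y axis), 1 point per gene, with genes at 0 in a library not drawn. Purple points are the genes that met the size rule in the same direction in both fractions (561 higher, 550 lower) and grey points met it in 1 fraction or oppositely; Clu lies at 1350.2-fold in crypts and 127-fold in whole epithelium.

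Lists of cell division genes stood low. Of 25 measured G2 and M phase genes in crypts, 15 met the size rule lower and 0 higher (median log2 ratio -1.61, -1.83 to -1.51; percentile 0 among random lists), and in whole epithelium 12 of 22 were lower (-3.08, -3.65 to -2.69; percentile 0). Nusap1, a spindle protein gene, was 5.68-fold lower in crypts (4.97 to 6.51) and 12.5-fold in whole epithelium (8.91 to 18.2), and Ccnb2, a mitotic cyclin gene, 4.25-fold (3.86 to 4.69) and 15.6-fold (11.5 to 21.9). Of the S phase genes, 2 of 25 were lower in crypts (median -0.49, -0.74 to -0.39; percentile 1.04) and 6 of 23 in whole epithelium (-2.06, -2.34 to -1.33; percentile 0). Tyms, which makes thymidylate, was 2.21-fold lower in crypts (2.05 to 2.39) and 4.73-fold in whole epithelium (3.93 to 5.73), and Rrm1, a ribonucleotide reductase gene, 2.11-fold (1.94 to 2.31) and 6.02-fold (4.78 to 7.68). Transit-amplifying-like cells were 0.459% against 24.5% of crypt cells beside these values, and 10 of the G2 and M genes were among the markers that named them.

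Of 14 measured stem cell genes in crypts, 2 were higher, 3 lower and 9 neither (median -0.96, -2.34 to 0.04; percentile 0.02), and in whole epithelium 2, 3 and 7 of 12 (-1.23, -2.70 to 0.43; percentile 0.01). Smoc2 was 5.76-fold lower in crypts (5.1 to 6.53), and the sodium-potassium-chloride cotransporter gene Slc12a2 2.12-fold and 4.32-fold lower in crypts and whole epithelium. Lgr5, a gene that marks crypt base stem cells, was at 3.01 CPM in irradiated and 13.4 in normal crypts, and Olfm4 at 0.0482 and 6.1, both under the 20 CPM of the size rule. The list's direction turned in enterocyte-like cells alone, to a median of 0.38 in crypts and 0.83 in whole epithelium. With equal makeup of enterocyte-like, goblet-like and T or NK-like cells, it was 0.01 in whole epithelium. Neither setting holds stem-like or transit-amplifying-like cells. Wnt targets, 6 of which are also in the stem cell list, had 3 of 13 members higher in crypts (median 0.88, -0.27 to 1.51; percentile 100) and 3 of 10 in whole epithelium (0.57, -0.37 to 1.39; percentile 98.7). Cd44, a hyaluronan receptor gene, was 4.92-fold higher in crypts (4.6 to 5.27) and 2.62-fold in whole epithelium (2.3 to 2.99), and Sox9 2.11-fold (2 to 2.23) and 2.81-fold (2.59 to 3.05). Notch pathway genes had 1 of 8 members lower in crypts (median -0.15; percentile 50.1) and 1 of 8 higher in whole epithelium (-0.03; percentile 77.2). The Notch feedback inhibitor gene Nrarp was 2.68-fold lower in crypts (2.37 to 3.04), and Hes1 met the rule in neither fraction.

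Damage and regeneration lists stood high. Targets of p53 had 11 of 26 members higher and 0 lower in crypts (median 1.15, 0.50 to 1.42; percentile 100) and 8 of 24 higher in whole epithelium (0.75, 0.48 to 1.53; percentile 99.99). Cdkn1a, the cell-cycle inhibitor p21, was 2.87-fold higher in crypts (2.78 to 2.96) and 2.89-fold in whole epithelium (2.78 to 2.99), Phlda3, an inhibitor of Akt, 58.7-fold (44.5 to 79.1) and 23.2-fold (17.2 to 32), and the kinase gene Plk2 13.7-fold (11.3 to 16.8) and 13.9-fold (11 to 17.9). Fetal and regenerative genes had 12 of 13 members higher in crypts (5.19, 2.49 to 8.89; percentile 100) and 7 of 11 in whole epithelium (3.58, 1.90 to 6.82; percentile 100), 2 of the crypt members being at 0 in normal crypts and entered at their bound. Besides Ly6a, Anxa1 and Sprr1a, they included Anxa8, 475-fold higher in crypts (162 to 2308). YAP targets had 5 of 11 members higher in crypts (1.78, -0.14 to 3.42; percentile 100) and 3 of 11 in whole epithelium (1.48, 0.72 to 2.16; percentile 100). F3, the tissue factor gene, was 10.7-fold higher in crypts (9.05 to 12.7), Nt5e, an ectonucleotidase gene, 20.5-fold (15.9 to 26.8), and Nuak2 3.91-fold (3.65 to 4.19). The revival stem cell list had 7 of 11 members higher in crypts (2.64, 0.40 to 9.35; percentile 100) and 5 of 11 in whole epithelium (2.87, 0.72 to 6.82; percentile 100). It was taken from what is known of the study itself and is not independent evidence, and with Basp1, 41-fold higher in crypts (31.8 to 53.9), it shares Anxa1, Ly6a, Cd44 and Cdkn1a with the lists above. Matrix and adhesion genes had 8 of 16 members higher in crypts (1.17, 0.53 to 2.96; percentile 100) and 4 of 16 in whole epithelium (0.94, 0.18 to 1.90; percentile 99.99). Among them Lamc2, a laminin chain gene, was 17.8-fold higher in crypts (15.6 to 20.3) and 15-fold in whole epithelium (12.5 to 18), and Plaur, the urokinase receptor gene, 29.7-fold in crypts (22 to 41.1).

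Interferon response genes stood high in both fractions, with 19 of 27 members higher and 1 lower in crypts (median 2.31, 1.22 to 3.99; percentile 100) and 20 of 25 higher and 2 lower in whole epithelium (2.17, 1.40 to 3.22; percentile 100). Zbp1, a nucleic acid sensor gene, was 32-fold higher in crypts (28.6 to 35.9) and 26.3-fold in whole epithelium (23.7 to 29.2), the ubiquitin-like modifier gene Isg15 30.7-fold (27.8 to 33.9) and 21.8-fold (19.7 to 24.1), and Ifit1 22.4-fold (19.8 to 25.6) and 10.3-fold (9.21 to 11.4). MHC class II genes had 4 of 5 members higher in crypts (2.83, 0.42 to 2.93; percentile 100) and 2 of 5 in whole epithelium (0.94, -0.97 to 1.85; percentile 98.0). Cd74, the invariant chain gene, was 7.39-fold higher in crypts (7.01 to 7.81) and 3.6-fold in whole epithelium (3.34 to 3.87), and H2-Ab1 5.58-fold (5.19 to 5.99) and 3.06-fold (2.83 to 3.31), beside myeloid-like shares of 1.47% against 0.217% in crypts. Within enteroendocrine-like crypt cells Cd74 was also at 153 against 2.04 CPM (170 and 3 counts), a value chosen after it was seen. Whether cell makeup, free RNA or epithelial expression set these values was not tested. Antimicrobial genes went both ways, with 8 higher and 4 lower of 13 in crypts (2.71, -2.62 to 7.51; percentile 100) and 6 higher and 4 lower of 11 in whole epithelium (1.54, -3.63 to 3.57; percentile 99.97). S100a8 and S100a9, which encode neutrophil calprotectin and led a myeloid-like cluster, were at 53 and 30.1 CPM in irradiated and at 0 and 0.0156 CPM in normal crypts. NF-kB targets had 4 higher and 1 lower of 10 in crypts (0.89, -2.26 to 4.86; percentile 99.8) and 4 higher and 1 lower of 9 in whole epithelium (0.96; percentile 99.8). Cxcl2, a neutrophil chemoattractant gene that led the same myeloid-like cluster, was at least 948-fold higher in crypts, Tnfaip3, an inhibitor of NF-kB, 3.6-fold, and the thymus-expressed chemokine gene Ccl25 4.8-fold lower (4.66 to 4.96). With members of at least 50 CPM alone, the crypt medians of the antimicrobial and NF-kB lists turned to -0.64 and -0.62. Immediate early genes had 1 higher and 1 lower of 20 in crypts (0.05; percentile 83.7) and 3 higher of 20 in whole epithelium (0.57; percentile 99.4). They are induced by tissue dissociation too.

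**Figure D3:**
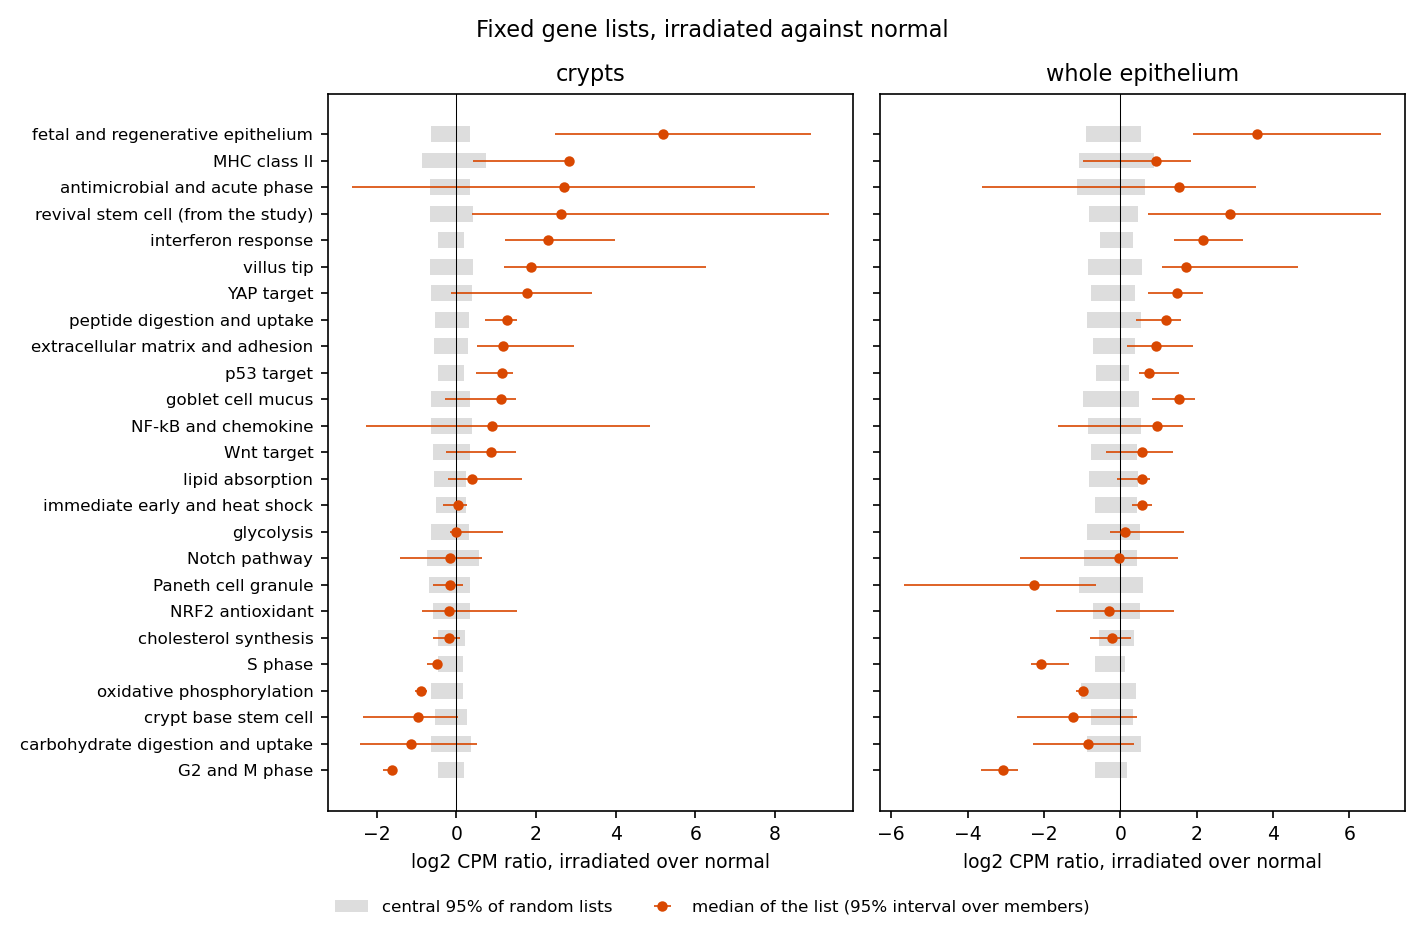
Median log2 ratio of CPM, irradiated over normal, of the measured members of 25 gene lists (x axis) in crypts and whole epithelium, with horizontal lines for the 95% interval over members and grey bars for the central 95% of random lists matched on expression. The fetal and regenerative list lies at 5.19 in crypts and 3.58 in whole epithelium, and the G2 and M phase list at -1.61 and -3.08.

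Among secretory lists, goblet genes had 8 of 15 members higher and 0 lower in crypts (median 1.13, -0.28 to 1.49; percentile 99.96) and 10 of 15 higher in whole epithelium (1.54, 0.84 to 1.97; percentile 100). The secreted mucin gene Muc2 was 2.87-fold higher in crypts (2.84 to 2.91) and 3.85-fold in whole epithelium (3.81 to 3.89), and Zg16, a lectin of goblet granules, 2.81-fold (2.8 to 2.82) and 4.83-fold (4.81 to 4.85). Clca3a1 was 6.32-fold (5.48 to 7.31) and 10.1-fold (8.55 to 12.1) higher, beside goblet-like shares of 14.6% against 11.6% of whole-epithelium cells. In crypts the goblet-like share was 6.71% against 10.7% without the genes that differed and, with all variable genes, 9.60% against 6.76% at resolution 1 and 6.29% against 6.81% at resolution 2. At resolution 0.5 it was 0.0459% against 10.9%, but an unnamed cluster held 240 irradiated crypt cells there, so that value may reflect naming. Paneth genes had 2 of 15 members higher in crypts (-0.15; percentile 73.2) and 11 of 15 lower in whole epithelium (-2.26, -5.67 to -0.62; percentile 0). Defa3 was 2.45-fold higher in crypts (2.42 to 2.48), with a log2 ratio of -0.60 at equal makeup of classes that leave out Paneth-like cells, and Mmp7, the protease that activates alpha-defensins, 2.41-fold (2.35 to 2.47). In whole epithelium the lectin gene Itln1 was 4.17-fold lower (4.08 to 4.26) and the lysozyme gene Lyz1, chosen after its value was seen, 4.78-fold (4.70 to 4.86).

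Absorptive lists went apart. Peptide uptake genes had 10 of 17 members higher and 0 lower in crypts (median 1.28, 0.72 to 1.53; percentile 100) and 11 of 17 higher in whole epithelium (1.20, 0.41 to 1.60; percentile 99.99), with the neutral amino acid transporter gene Slc6a19 7.93-fold (7.63 to 8.24) and 6.1-fold (5.91 to 6.31) and the peptide transporter gene Slc15a1 5.71-fold (5.45 to 5.97) and 3.96-fold (3.8 to 4.13) higher. Villus tip genes had 11 of 11 members higher in crypts (1.89, 1.20 to 6.28; percentile 100) and 9 of 11 in whole epithelium (1.71, 1.09 to 4.64; percentile 100). Ada, which encodes adenosine deaminase, was 77.6-fold higher in crypts (71.1 to 84.8) and 25-fold in whole epithelium (23.3 to 26.9), and the nucleoside transporter gene Slc28a2 109.5-fold (87.5 to 139) and 30.4-fold (26.2 to 35.4). Lipid handling genes had 6 of 20 members higher in crypts (0.41; percentile 99.5) and 4 of 20 in whole epithelium (0.57; percentile 99.1), with the apolipoprotein genes Apoc2 15.1-fold (12.8 to 18) and 15.4-fold (13.7 to 17.4) and Apoa4 4.98-fold (4.93 to 5.02) and 2.88-fold (2.85 to 2.9) higher. Carbohydrate genes had 1 of 12 members higher and 6 lower in crypts (-1.12, -2.42 to 0.52; percentile 0.01) and in whole epithelium (-0.86, -2.28 to 0.36; percentile 2.67). The gluconeogenic gene Fbp1 was 11.8-fold lower in crypts (9.94 to 14.2) and 23.2-fold in whole epithelium (16.8 to 33.1), Sis, which encodes sucrase-isomaltase, 5.41-fold (5.26 to 5.55) and 4.85-fold (4.7 to 5.01), and the fructokinase gene Khk 5.36-fold (5.15 to 5.57) and 3.93-fold (3.76 to 4.11).

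Cholesterol synthesis genes had 2 of 20 members lower in crypts (-0.17; percentile 38.5) and 1 higher and 2 lower of 19 in whole epithelium (-0.21; percentile 33.5), Dhcr7 being 2.48-fold and 2.36-fold lower. NRF2 targets had 3 higher and 2 lower of 14 in crypts (-0.17; percentile 46.0) and 3 higher and 4 lower in whole epithelium (-0.29; percentile 25.7). Gpx2, an epithelial glutathione peroxidase gene, was 11.6-fold (11.5 to 11.8) and 15.1-fold (14.8 to 15.4) higher, while Gstm1 was 5.37-fold (4.91 to 5.87) and 8.76-fold (7.61 to 10.1) lower. Oxidative phosphorylation genes had 0 higher and 8 of 24 lower in crypts (-0.88, -1.04 to -0.74; percentile 0) and 11 of 24 lower in whole epithelium (-0.99, -1.15 to -0.89; percentile 3.83). The ATP synthase gene Atp5g1 was 3.18-fold (3.13 to 3.23) and 3.77-fold (3.68 to 3.86) lower and the succinate dehydrogenase gene Sdha 2.82-fold and 2.37-fold. Glycolysis genes had 2 of 15 higher in crypts (-0.01; percentile 76.1) and 2 higher and 1 lower in whole epithelium (0.11; percentile 82.1), with the hexokinase gene Hk2 3.17-fold (3 to 3.35) and 5.12-fold (4.79 to 5.47) higher. Of the sex-linked genes Xist alone was measured, at 731 and 468 CPM in normal and irradiated whole epithelium and 878 and 641 in crypts, and Ddx3y had 0 counts in all 4 libraries. Across all lists, 14 in crypts and 15 in whole epithelium lay above the central 95% of random lists, and 5 and 4 below it. With members of at least 50 CPM alone, 9 lists lay above it in whole epithelium and 2 below it in crypts.

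Within classes the libraries differed as well. Irradiated enterocyte-like crypt cells (858, in clusters 1, 3 and 11, against 598 normal ones, all but 1 in clusters 2, 6 and 9) had 781 genes higher and 1004 lower, of which 1033 were shared in direction with the genes from all cells. Genes in this paragraph were chosen after their values were seen. The chloride channel regulator gene Clca4a stood at 878 against 1.28 CPM there, and the water channel gene Aqp8 at 0 counts against 56.5 CPM, at least 263-fold lower. In whole epithelium, enterocyte-like cells had 789 genes higher and 995 lower, 1383 of them shared. The amino acid transporter gene Slc6a14 was at 51.1 CPM against 0 counts, at least 248-fold higher, and Hk2 at 157 against 1.51 CPM. Goblet-like crypt cells (209, mostly cluster 8, against 156, mostly cluster 12) had 344 genes higher and 733 lower, with Sprr2a3 at 468 against 8.06 CPM and the actin-severing gene Scin at 32.0 against 620. In whole epithelium goblet-like cells had 236 genes higher and 421 lower, with Il33, an alarmin gene, at 31.9 against 1.69 CPM and the antimicrobial lectin gene Reg3b at 12195 against 800. The irradiated goblet-like crypt cells included 53 cells with over 5% of their UMIs from Defa24 and little Defa20, and 3 with more Defa20. Enteroendocrine-like crypt cells (96 and 73, in clusters both treatments shared) had 581 genes higher and 603 lower. Ada stood at 416 against 6.13 CPM, and the cycling genes Mki67 at 2.71 against 110 and Hist1h2ap at 18.0 against 855, while the T-cell gene Nkg7 was at 30.7 against 0.681. T or NK-like cells had 164 genes higher and 105 lower in crypts, and 215 and 101 in whole epithelium. Cluster 4 held 402 irradiated and 1 normal of these crypt cells and cluster 16 held 2 and 70, while cluster 7 was shared, with 237 and 49. In whole epithelium these clusters held 107 and 2, 0 and 88, and 51 and 69. Their higher genes held S100a6, at 575 against 32.9 CPM in crypts, and also the enterocyte gene Slc6a19, at 117 CPM against 0 counts.

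Clu UMIs were found in cells of the irradiated libraries at shares that differed between classes. At 2000 UMIs per cell, 15.5% (13.7 to 17.4; 230 of 1487) of cells in epithelial clusters of irradiated crypts had a Clu UMI and 0 of 2141 in normal crypts, which allows up to 0.140%. In irradiated whole epithelium it was 3.59% (2.43 to 5.08; 30 of 836) and in normal whole epithelium 0.0552% (0.00140 to 0.307; 1 of 1811). T or NK-like cells, which should lack Clu and so measure free RNA, had it in 8.30% (6.31 to 10.7) of irradiated crypt cells, 0.629% (0.0159 to 3.45) of irradiated whole-epithelium cells, and 0 of 118 and 0 of 160 cells in normal crypts and whole epithelium. Median depths were 16847 UMIs in epithelial and 3631 in T or NK-like cells of irradiated crypts, and 16059 and 4494.5 in irradiated whole epithelium. Without thinning the epithelial shares were 60.7% and 17.7% in the irradiated and 0.416% and 0.385% in the normal crypts and whole epithelium, and 17.5% and 1.85% of T or NK-like cells in the irradiated libraries. In irradiated crypts the epithelial share was 9.55% at 1000 and 25.6% at 4000 UMIs per cell, and 3.70% for at least 2 Clu UMIs, and in irradiated whole epithelium 1.66%, 5.38% and 0.239%. Thinning left out 72 epithelial cells of irradiated whole epithelium, 6 of normal whole epithelium, 25 of normal crypts and 0 of irradiated crypts.

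By class, 16.7% (9.84 to 25.7) of enteroendocrine-like, 13.4% (9.09 to 18.8) of goblet-like and 12.2% (10.1 to 14.6) of enterocyte-like cells of irradiated crypts had a Clu UMI at this depth. These intervals overlap that of T or NK-like cells, but overlap does not show equal shares. Nor does it decide how much is free RNA, since thinning kept a larger part of the shallower T or NK-like cells. Their median depth was 3631 UMIs, against 14519 in enterocyte-like cells. Without thinning, 663 T or NK-like cells held 131 Clu UMIs (17.5% of cells with any) and 858 enterocyte-like cells held 874 (52.6%). The revival stem-like share after thinning was 32.1% (26.5 to 38.1), but Clu is among the markers that named this cluster. In CPM, Clu stood at 636 in revival stem-like, 244 in goblet-like, 62.7 (58.6 to 67.0) in enterocyte-like, 62.2 (48.4 to 78.8) in enteroendocrine-like and 44.7 (37.4 to 53.1) in T or NK-like cells of irradiated crypts. These values are sums over cells, which cells with many Clu UMIs can set. Goblet-like and enterocyte-like cells differed in CPM but little in the share with a Clu UMI (13.4% and 12.2%). Ly6a stood at 1005 CPM in revival stem-like, 387 in goblet-like, 301 in enteroendocrine-like, 154 in enterocyte-like and 81.9 in T or NK-like cells. In irradiated whole epithelium, Clu was at 109 CPM in revival stem-like, 16.0 (13.7 to 18.5) in enterocyte-like, 8.95 in goblet-like and 3.71 (0.765 to 10.8) in T or NK-like cells. Of enterocyte-like cells there 2.38% (1.31 to 3.96) had a Clu UMI after thinning. This interval also overlaps that of T or NK-like cells, which were again shallower, so the overlap decides nothing either. The intervals in CPM of enterocyte-like and T or NK-like cells did not overlap in either irradiated library.

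**Figure D4:**
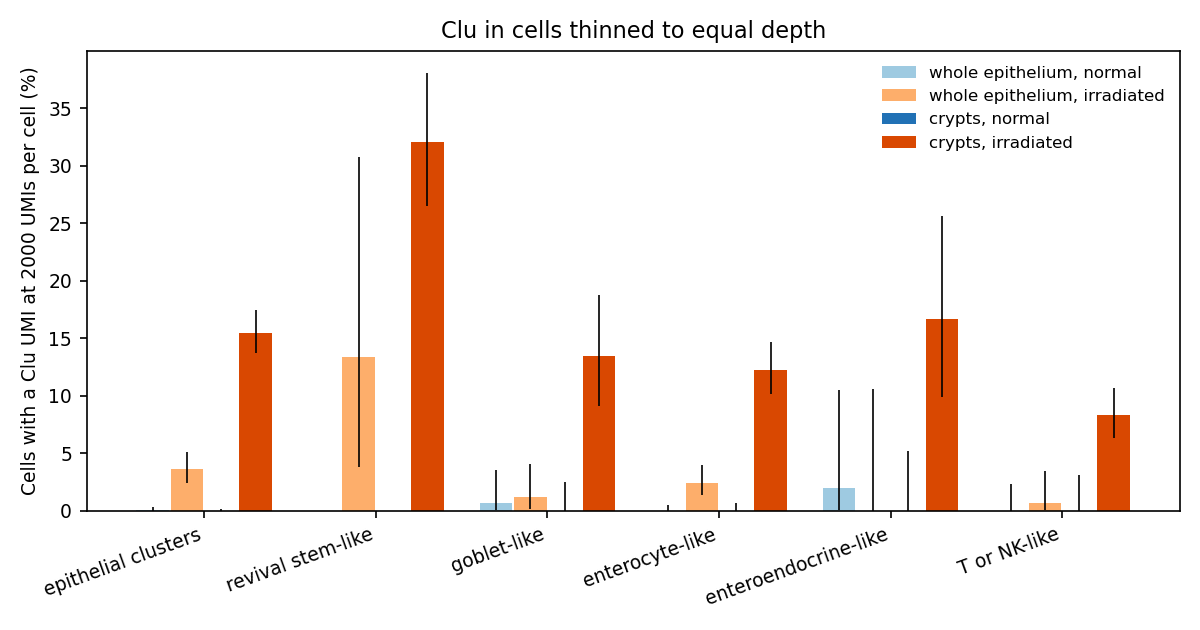
Share of cells (%) with at least 1 Clu UMI after thinning to 2000 UMIs per cell, by cell class and library. Bars are shares and error bars exact 95% binomial intervals (counting error only); the epithelial bar of irradiated crypts stands at 15.5% and the T or NK-like background at 8.30%.

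Between the normal fractions, AY761184 and Defa23, alpha-defensin genes, were higher in crypts and Ccl5 and Sct lower. Of 5191 genes, 17 met the size rule higher and 65 lower in normal crypts than in normal whole epithelium, under the stricter cell filter 4 did so higher, and without the minimum CPM 51 and 352 did. The 17 comprised 4 globin genes, alpha-defensin genes, and Clps, Ang4 and Mmp7. AY761184 (chromosome 8, 21702519 to 21703645) was 2.91-fold higher (2.89 to 2.93) and Defa23 2.74-fold (2.69 to 2.8). The 65 lower included Nkg7, Cd8a and Gzma of lymphocytes and Slc6a19, Ace and Lct of enterocytes, named after their values were seen. Among them Ccl5 was 2.20-fold lower (2.16 to 2.24) beside a T or NK-like share of 5.29% against 8.09%. Secretin (Sct) was 2.95-fold lower (2.87 to 3.03). Clu was at 0.187 and 0.172 CPM, 1.09-fold (0.395 to 3.26), a difference not detectable at this depth.

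Between the irradiated fractions, alpha-defensin genes differed by unequal folds. Gm21002 was at 3194 CPM in irradiated crypts and 20.6 in irradiated whole epithelium, 155-fold higher (141 to 172), Defa23 128-fold (107 to 155) and AY761184 56-fold (53 to 59.3), whereas Defa24 and Defa17, chosen after their values were seen, were 3.27-fold and 2.28-fold higher. Clu was 11.5-fold higher in irradiated crypts (10.5 to 12.8), Sprr1a 6.11-fold (5.32 to 7.04), Anxa1 4.38-fold (3.86 to 4.99) and Ly6a 2.54-fold (2.45 to 2.64). Ghrl, which encodes the hormone ghrelin, was 18.5-fold lower (17.6 to 19.4) and Afp 4.00-fold (3.71 to 4.33), and the goblet genes Zg16 and Muc2 2.77-fold (2.76 to 2.78) and 2.23-fold (2.21 to 2.25). Ghrl and Afp were leading genes of 2 enteroendocrine-like clusters, with 44 and 52 irradiated crypt and 17 and 19 irradiated whole-epithelium cells. Few cells could therefore set their ratios. In all, 228 of 5146 genes met the size rule higher and 68 lower, and 475 and 29 did with all barcodes, 528 and 44 with the barcodes of the authors' tables, and 1094 and 204 without the minimum CPM. The stricter cell filter left 108 lower. In both treatments 12 genes were higher in crypts and 5 lower, the latter Prr15, Pck1, Plb1, Cfb and Ghrl. The gluconeogenic gene Pck1 was 2.23-fold lower in normal (2.1 to 2.37) and 2.38-fold in irradiated crypts (2.07 to 2.72), and the complement gene Cfb 2.11-fold (1.93 to 2.32) and 2.65-fold (2.45 to 2.86).

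Alpha-defensin genes also differed among themselves. Defa24, chosen after its values were seen, was at 16224 and 10522 CPM in normal and irradiated whole epithelium and 32300 and 34421 in crypts, while Defa20 was at 2911, 52, 4739.6 and 4896. As a share of Defa24, Defa20 was 17.9%, 0.495%, 14.7% and 14.2%. Cells with over 5% of their UMIs from Defa24 were divided by whether Defa20 reached 5% of Defa24. Defa20-rich cells by this measure were 45.2% (34.8 to 55.8; 42 of 93) in normal whole epithelium and 9.52% (1.17 to 30.4; 2 of 21) in irradiated whole epithelium. They were 62.9% (56.7 to 68.7; 166 of 264) in normal crypts and 34.7% (25.3 to 45.2; 33 of 95) in irradiated crypts. Within 1.5-fold of the dividing value lay 4, 1, 39 and 6 cells of these libraries in the same order. With a Defa24 limit of 2% the Defa20-rich shares were 65.2%, 5.88%, 74.5% and 36.4%, and with 10% they were 48.1%, 7.14%, 61.9% and 38.4%. Defa20 in T or NK-like cells, which may be free RNA, stood at 2287, 16.1, 2280 and 600 CPM. Free RNA could therefore raise the Defa20-rich share more in the normal libraries than in the irradiated ones. The split is a range and not a cell type, and the class that held these cells depended on the clustering. In irradiated whole epithelium 79.5% of Defa24 UMIs were in goblet-like cells with all variable genes, and 18.5% without the genes that differed.

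**Figure D5:**
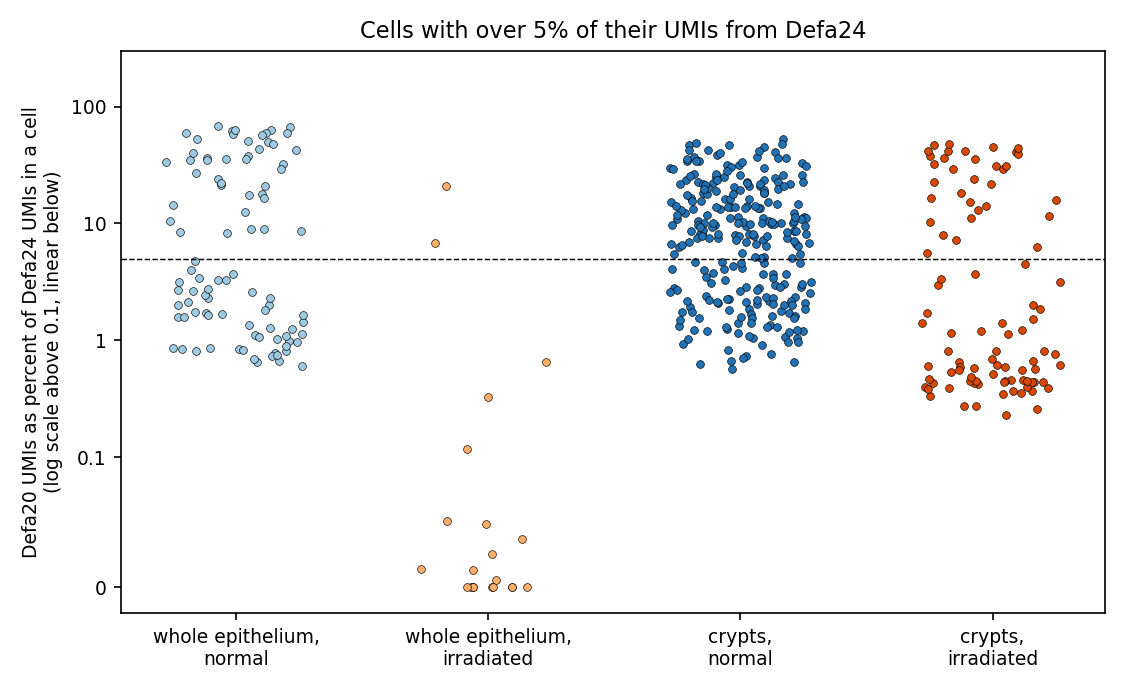
Defa20 UMIs as a percentage of Defa24 UMIs (y axis, log scale above 0.1) for each cell with over 5% of its UMIs from Defa24, by library. Each point is a cell and the dashed line marks 5%; 2 of 21 cells of irradiated whole epithelium and 42 of 93 of normal whole epithelium lie at or above it.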

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

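The tests of the alpha-defensin pattern in this part were chosen after its result was seen.

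Gm10104, an alpha-defensin gene on chromosome 8 (21065038 to 21065996), stood apart between the fractions. Its log2 ratio of irradiated over normal was 2.71 in crypts (3279 CPM in the irradiated and 501 in the normal library) and -1.17 in whole epithelium (192 and 433 CPM). Gm15293 (21201561 to 21202539) had log2 ratios of 1.17 in crypts and -2.41 in whole epithelium, with 3029 and 1342 CPM in irradiated and normal crypts and 102 and 541 in whole epithelium. Each difference between the fractions rests on 1 library per group, and the difference was not tested. Both genes belong to a family of near-identical copies.

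The alpha-defensins of irradiated whole epithelium also differed from each other, Defa20 being 0.495% of Defa24 there and 17.9% in normal whole epithelium. Defa20-rich cells were 9.52% (2 of 21 cells; 1.17 to 30.4) of the Defa24-rich cells there and 45.2% (34.8 to 55.8) in normal whole epithelium, but the split is made by Defa20 itself and restates the ratio. Fewer cells of that kind therefore cannot be told apart from less Defa20 in each cell. Defa20 in the Defa20-poor cells stood at 120 CPM in irradiated and 2167 in normal whole epithelium, the latter below the 2287 CPM of T or NK-like cells, and so decides nothing either. The ratio reached at most 1.01% in any class of that library with at least 20 cells, but outside Defa24-rich cells such UMIs may be free RNA that repeats 1 ratio, and the animals' genotype, reads shared between paralogs and irradiation cannot be told apart with 1 library per group.

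Clu was also found in barcodes that the cell filter left out. In irradiated crypts these 2304 barcodes held 811 Clu UMIs, at 68.9 CPM (64.2 to 73.8), and those of normal crypts stood at 0.231 CPM. In irradiated whole epithelium they held 147 Clu UMIs, at 9.16 CPM (7.74 to 10.8), against 0.303 CPM in normal whole epithelium.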

How the results depend on the processing

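Settings that used single classes or epithelial clusters alone were added after the data were seen; all others were fixed before. Under TMM scaling, all 8 counts of genes stayed within 1.5 times their value (crypts 703 higher and 675 lower, whole epithelium 846 and 871), and the same held for irradiated against normal with equal cell makeup and with epithelial clusters alone. Of the other values, 84 of class shares moved beyond their interval over all settings and 180 did not, 30 medians of gene lists moved, 5 reversed and 275 did neither, and for single named genes 847 ratios moved, 1 reversed and 938 did neither. Where a value moved, the cause was not tested, except that dropping the minimum expression or summing fewer cells changes how many genes can meet the rule. For irradiated against normal crypts, no minimum CPM gave 2906 higher and 1753 lower, goblet-like cells alone 344 higher, enterocyte-like cells alone 1004 lower, and T or NK-like cells alone 164 and 105. For whole epithelium, no minimum CPM gave 1852 and 2455, goblet-like cells alone 236 and 421, and T or NK-like cells alone 215 and 101. For normal crypts against whole epithelium, no minimum CPM gave 51 higher and 352 lower, and the stricter cell filter 4 higher. For the irradiated pair, no minimum CPM gave 1094 and 204, all barcodes gave 475 and 29, 528 and 44 came from the barcodes that the authors' tables hold, and the stricter filter gave 108 lower. With list members of at least 50 CPM, 2 lists lay below the random range in crypts and 9 above it in whole epithelium, and the crypt medians of the antimicrobial and NF-kB lists reversed to -0.64 and -0.62. In enterocyte-like cells alone, 3 lists lay below in crypts, and the stem cell list reversed to 0.38 in crypts and 0.83 in whole epithelium. With equal cell makeup it reversed to near 0, 0.01 (0.00850), in whole epithelium, and Defa3 reversed to -0.60 in crypts. The classes these settings use leave out stem-like, transit-amplifying-like and Paneth-like cells, so they say nothing of these genes in such cells. In irradiated crypts, T or NK-like cells were 15.4% of all barcodes and 40.8% under the stricter filter, revival stem-like cells 6.58% and 14.3%, and transit-amplifying-like cells 0.459% without the genes that differed. Under the stricter filter no cluster was named transit-amplifying-like or stem-like, so those shares could not be compared there. The largest unnamed cluster in that setting held 166 normal whole-epithelium, 375 normal crypt and 1 irradiated crypt cells. The Clu share of epithelial cells in irradiated crypts was 9.55% at 1000 UMIs, 25.6% at 4000, 60.7% without thinning, 3.70% for at least 2 UMIs, 18.9% under the stricter filter and 12.3% among all kept cells. In irradiated whole epithelium it was 1.66%, 5.38%, 17.7% and 0.239% in the first 4 of these. In normal whole epithelium it was 0% at 4000 UMIs, for at least 2 UMIs, with doublets kept and under the stricter filter, and 0.385% without thinning, and in normal crypts 0.416% without thinning. Settings for stem-like and transit-amplifying-like cells were not run, since irradiated crypts held 1 such cell. Depth limits the Clu share, since thinning to 2000 UMIs drops most UMIs of epithelial cells, whose median depth in irradiated crypts was 16847.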

Other observations

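Genes in the first 2 paragraphs were chosen after their values were seen. Of the tests below, those of free RNA and attached cells for cells rich in Defa24 were chosen after the result was seen, and those of random doublets and of enterocyte-like cells before their results were seen.

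Genes of enteroendocrine hormones stood apart from each other. Pyy (peptide YY) was 29.2-fold higher in irradiated than in normal crypts (27.0 to 31.8) and 21.9-fold in whole epithelium (19.6 to 24.5), and Iapp (amylin) 18.8-fold (16.5 to 21.6) and 19.2-fold (16.1 to 23.0). Nts (neurotensin) was 24.5-fold higher in crypts (23.1 to 26.0) and 4.38-fold in whole epithelium (4.11 to 4.67), and Sst (somatostatin) 3.59-fold (3.51 to 3.69) and 8.02-fold (7.76 to 8.30). Ghrl (ghrelin) was 5.78-fold higher in whole epithelium (5.60 to 5.96) and at 42.6 against 66.9 CPM in crypts. Cck (cholecystokinin) was 2.26-fold lower in whole epithelium (2.20 to 2.34) and at 419 against 243 CPM in crypts. Enteroendocrine-like cells were 3.35% against 2.61% of whole epithelium and 4.36% against 3.16% of crypts. With all variable genes they were 36 irradiated and 51 normal whole-epithelium cells and 96 irradiated and 73 normal crypt cells. The ranges above do not cover which of these cells were captured, so few cells could set the ratios of single hormones.

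Duox2 and Duoxa2, the epithelial NADPH oxidase and its maturation factor, were 6.53-fold (6.03 to 7.08) and 11.2-fold (9.92 to 12.6) higher in irradiated crypts and 6.87-fold (6.25 to 7.57) and 11.8-fold (10.2 to 13.8) in whole epithelium. Gsdmd, which encodes the pore-forming gasdermin D, was 6.08-fold (5.86 to 6.32) and 5.33-fold (5.12 to 5.54) higher, and Areg, an EGF receptor ligand, 12.1-fold (11.3 to 13.1) and 16.1-fold (14.7 to 17.6). Of bile acid genes, Slc10a2, the ileal uptake transporter, was 8.97-fold (8.05 to 10.0) and 5.47-fold (4.97 to 6.03) higher, whereas Fabp6, the ileal bile acid binding protein, was 3.15-fold (3.11 to 3.19) and 4.66-fold (4.59 to 4.74) lower. Aldh1a1, which makes retinoic acid, was 13.3-fold (12.5 to 14.2) and 12.2-fold (11.4 to 13.2) lower, and the transferrin receptor gene Tfrc 4.15-fold (3.87 to 4.45) and 7.14-fold (6.24 to 8.19).

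Cells rich in Defa24 but poor in Defa20 carried goblet genes in the irradiated libraries. The median cell of this kind had 0.580% of its UMIs from Muc2 in irradiated and 0.0508% in normal crypts, and 1.10% and 0.0548% in irradiated and normal whole epithelium. Free RNA does not account for it in irradiated crypts, where Muc2 was 12.6-fold above its level in T or NK-like cells. Doublets stay open: enterocyte marker genes, which doublets formed at random would bring at least as often as goblet genes, were over 3 times the free-RNA level in 12.9% of these cells against 79.0% (49 of 62) for goblet genes, but 70.6% of simulated doublets passed that level, too few by the limit set in advance. Goblet-like cells still attached to Defa24-rich cells cannot be told apart from single cells with both sets of genes: the median of 47101 UMIs was 2.90 times that of goblet-like cells not rich in Defa24, but the 13 cells without goblet genes over that level were as deep (48790), so depth decides nothing, and no biological explanation was tested.

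Irradiated and normal enterocyte-like cells fell into different clusters. At 516228 summed UMIs per library, 1181 genes met the size rule between irradiated and normal enterocyte-like crypt cells, 874 within enteroendocrine-like and 240 within T or NK-like cells. T or NK-like cells shared 11.8% of the enterocyte-like genes in direction. This lay below the limit set in advance against free RNA of another makeup as the whole source. Free RNA is still not excluded, since a gene shifted alike in both classes can miss the size rule in 1 of them. The 139 shared genes were 57.9% of the T or NK-like genes and may come from free RNA. A shift of the whole library cannot be told apart from a difference in enterocytes, because the enteroendocrine-like count was 74.0% of the enterocyte-like one and the T or NK-like count 20.3%, on either side of the limits set in advance. Enteroendocrine-like cells shared 30.6% (361) of the enterocyte-like genes in direction, which were 41.3% of their own. This overlap decides nothing, since a gene shifted alike in both classes can still miss the size rule in 1 of them.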
